A study of Zea mays with 12 samples.

How the data were processed

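Messenger RNA was measured by RNA-seq in maize seedlings mutant for Rgh3 (rough endosperm3; the genotype is called rgh3 in the labels) and in their wild-type siblings. Roots and shoots were taken apart, with 3 replicates of each genotype and tissue, which gives 12 libraries in 4 groups. Per the labels' protocols, seedlings were grown to 2 inches, RNA was extracted with TRIzol, and libraries were made with the TruSeq RNA kit from 2 ug of input RNA with inserts of a median of 200 bp. The 12 libraries were pooled and sequenced on 1 lane of an Illumina HiSeq as paired reads of 100 bp. The labels give replicate numbers and no harvest day, plant or pool. Nothing in them says that replicates came from separate plants, so the limma p-values of single genes, introns and transcripts measure only the spread between these samples.

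The deposited values are FPKM per transcript, written by Cufflinks together with estimated coverage, confidence limits and other attributes for each transcript. Per the submitters' processing notes the tools were Bowtie 0.12.7, Picard 1.54, GSNAP, Cufflinks 1.3.0 and Cuffdiff; the role and order of each tool and the genome build are not given in the sources used here. All 12 libraries were quantified by the authors against the same 63210 transcripts of 39401 genes on chromosomes 1 to 10, of which 12641 genes had 2 or more transcripts. The deposited FPKM of a library summed to between 1.48e+10 and 2.43e+10, so the denominator was not mapped fragments in units of 1e+06. The 75th percentiles of the values above 0 lay close together, from 295726 to 320644, as an upper-quartile option of Cufflinks would give; which option was used is not stated. Every value was therefore divided by one common constant, 20029, which brings the mean library sum to 1e+06 and leaves every ratio between libraries as deposited. FPKM below means this rescaled value, and the thresholds apply to it.

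Depth was estimated per library from the deposited coverage times transcript length, divided by the 200 bases that a read pair covers. For genes with a single transcript this estimate was 0.976 to 1.01 times the one implied by the Cufflinks confidence limits. With M for 1e+06, it gave 10.3, 2.98 and 7.46 M fragments for wild-type root replicates 1, 2 and 3, and 7.14, 8.02 and 7.89 M for the wild-type shoot replicates. The rgh3 root replicates had 5.58, 6.12 and 4.93 M fragments and the rgh3 shoot replicates 5.51, 4.24 and 0.455 M.

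Gene FPKM was the sum over a gene's transcripts. Genes with FPKM of 1 or more in at least 3 libraries were tested, which left 25714. The limma package (version 3.58.1, in R 4.3.3 with version 1.17.8 of data.table) was fitted with its trend option to log2(FPKM + 0.25), with 1 mean per group over all 12 libraries and a prior of 3.88 degrees of freedom. Comparisons were rgh3 against wild type in roots, in shoots and averaged over both tissues, the genotype by tissue interaction (shoot difference minus root difference), and roots against shoots within each genotype. Calls needed a Benjamini-Hochberg adjusted p under 0.05. The added 0.25 makes fold changes of genes with low values too small. Reads shared by near-identical gene copies were assigned by Cufflinks, and a strand-specific protocol is not named, so values of close copies and of overlapping genes on opposite strands are uncertain.

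Isoform usage was a transcript's share of its gene's FPKM, and the retained share of an intron was the FPKM of annotated transcripts that hold the intron inside an exon, as percent of those plus the transcripts that splice exactly that intron. Both are estimates over whole annotated isoforms, which can differ elsewhere too. Genes entered with a mean FPKM of 2 or more in each group. Transcripts had a mean share of 5 to 95% and introns one of 1 to 99%, which gave 17102 transcripts of 7129 genes and 6956 introns of 4497 genes, out of 10723 annotated introns of this kind in 6457 genes. The arcsine of the square root of each share was tested with limma in the same design.

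The reference table gives symbols for maize genes and matched 18771 of the 39401 gene identifiers (47.6%); 2618 genes had a symbol, and 520 identifiers matched more than 1 gene of the table. It gives no product names, and the 29 gene lists fixed before the data were examined mostly used them. After this table was seen and before any group comparison, 37 lists were written as symbol patterns. Of these, 23 continued the subject of a list fixed earlier, with other and in part wider or narrower members. The other 14 were added from the symbols found: oxylipins, terpene synthases, endoplasmic reticulum folding, autophagy, chromatin factors, potassium transporters, and the WRKY, EREB, NAC, MADS, homeobox, MYB, bHLH and bZIP families. For 5 of the earlier lists, among them the minor spliceosome and nonsense-mediated decay, no list was written, and they are not analysed here. A list needed 5 tested members, and 36 were tested with limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Positions are those of the deposited gene models; their build is not given in the sources used here. A planned comparison of introns with U12-type splice sites needs genome sequence and is not analysed here. The result for 1 called intron is not reported here.

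The test, filter, pseudocount, comparisons, alternatives and rule for named genes were fixed before the data were examined. The rule named Rgh3, and in roots and in shoots the 10 genes that rose most and the 10 that fell most among called genes with a symbol, no overlap between the 3 values of each genotype and a mean FPKM of 2 or more in 1 genotype. It also named the 5 largest interaction differences each way, the 6 largest tissue differences each way in wild type, up to 4 members of each list with the lowest p, the 10 largest share changes each way, and the 10 genes with the largest mean change among those called in the same direction in both tissues. A symbol took the place of the planned product name. For the interaction, non-overlap was asked in at least 1 tissue, a reading chosen after the calls were seen, and only 2 genes with a positive difference met it.

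Whether replicate numbers pair libraries was checked from correlations of values centred within each group. Same-number libraries correlated at 0.159 to 0.351 between the genotypes in shoots, 0.288 to 0.336 between tissues in wild type and 0.143 to 0.218 between tissues in rgh3, and were taken as paired. In roots the genotypes' same-number correlations ran from 0.0826 to 0.271, and there too each library correlated best with its own number. The root libraries were taken as unpaired only because the lowest value fell under the limit used. The reported fits had no block in any comparison. Their p-values in shoots, between tissues, averaged over tissues and for the interaction therefore ignore the pairing found here. Root p-values without a block may ignore a real pairing too. The highest correlation between different numbers was 0.00495. A fit with replicate number as a block was run for every comparison.

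Alternatives were pseudocounts of 1 and 0.05, an FPKM filter of 5 or none, a fold change of 2 or more, median ratio and quantile scaling, a fit of only the 2 groups compared, the replicate block, array weights, leaving out each library in turn, other share scales and filters, diffSplice on log2 FPKM, and an adjusted p under 0.01. Scaling to an equal sum of FPKM was added after the data were seen. The fits were tested on simulated data, in which 50 genes per fold were changed in libraries of 1 group. In the root comparison 0 genes changed 1.5-fold, 4 changed 2-fold, 19 changed 4-fold and 30 changed 8-fold were recovered, with 4 false calls among 25123 genes; in shoots the numbers were 0, 3, 21 and 27, with 5 false calls. Of 50 introns shifted by 25 points, 20 were recovered in roots and 21 in shoots, with 7 and 10 false calls. Overlaps were tested with Fisher's exact test, two-sided, and differences of medians with permutation tests of 100000 resamples, two-sided. Both take genes or introns as units, so their p-values do not measure the spread between libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.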

Results

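RNA was sequenced from roots and shoots of maize seedlings, in rgh3 mutants and in their wild-type siblings, with 3 replicate libraries of each genotype and tissue. Rgh3 encodes a splicing factor related to human ZRSR2, a protein of U12-type intron splicing, and the series sets the mutant's transcripts against those of its siblings. Estimated depth ran from 2.98 to 10.3 M fragments (M, 1e+06) in 11 libraries. It was 0.455 M in rgh3 shoot replicate 3, which listed 21631 genes above 0 against 25291 to 27746 in the others. Pearson's r between replicates, across genes, was 0.919 to 0.937 in wild-type roots, 0.934 to 0.942 in wild-type shoots, 0.890 to 0.909 in rgh3 roots and 0.806 to 0.906 in rgh3 shoots. Tissue separated the libraries on the component with 51.7% of the variance. The 100 most abundant genes took 13.8 to 19.2% of FPKM per library, with the highest share in rgh3 shoot replicate 3.

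**Figure D1:**
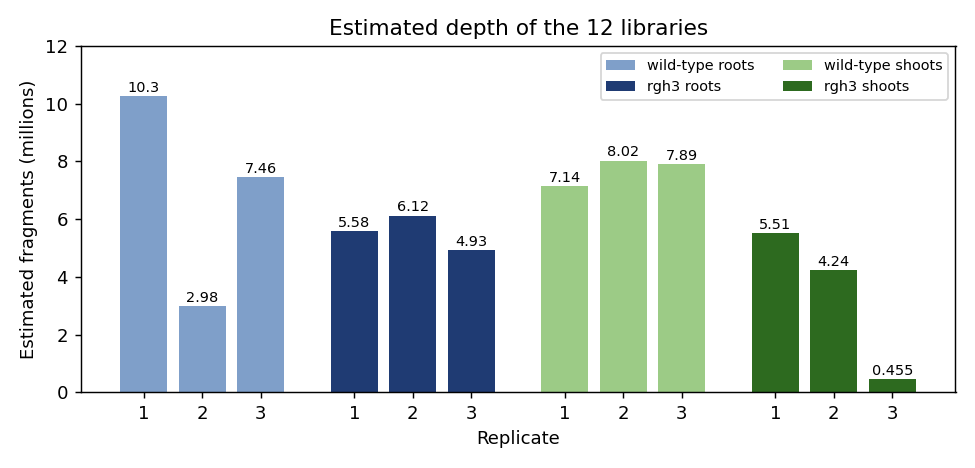
Bars give the estimated number of fragments in M (1e+06, vertical axis) for each of the 12 libraries (horizontal axis), grouped by genotype and tissue. The lowest bar is rgh3 shoot replicate 3 at 0.455 M, and the highest is wild-type root replicate 1 at 10.3 M.

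The reference table gives the symbol Rgh3 to 2 gene models on chromosome 5 (build not given in the sources used here). The model GRMZM2G128228, at 173695448 to 173696940 on the minus strand with 1 transcript, had a mean FPKM of 10.8 ± 1.24 (SD, n = 3) in wild-type roots and 11.5 ± 2.99 in rgh3 roots. In shoots it had 5.57 ± 0.649 in wild type and 7.71 ± 0.432 in rgh3. Neither difference passed the limma test (log2 0.06, SE 0.28, adjusted p = 0.956 in roots; log2 0.46, SE 0.28, adjusted p = 0.439 in shoots). The model GRMZM5G849788, at 173758062 to 173761169, had FPKM of 2.40, 2.16 and 3.95 in the wild-type root replicates and 8.10, 7.72 and 10.5 in the rgh3 root replicates (log2 1.58, SE 1.00, adjusted p = 0.460). It had 1.74, 1.82 and 1.05 in wild-type shoots, and in rgh3 shoots 5.43 and 7.62 in replicates 1 and 2 and was listed at 0 in replicate 3 (log2 0.35, adjusted p = 0.896). Its root values did not overlap between the genotypes. The fit shares each gene's spread over all groups, so the 0 in rgh3 shoot replicate 3 also widens the SE in roots. The root test therefore does not show that the genotypes were alike. Each model had 1 annotated transcript, so neither value bears on the structure of the mutant transcript.

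Introns were retained more in the mutant, which is the comparison closest to a splicing factor's role. In roots 37 introns of 33 genes changed, 37 with a higher and 0 with a lower retained share in rgh3. In shoots 30 introns of 26 genes changed, 28 higher and 2 lower. The median retained share of the root introns was 6.00% in wild type and 53.1% in rgh3, and that of the 28 shoot introns was 5.67% and 59.9%. Over all 6956 tested introns the medians were 16.4% and 19.9% in roots and 14.5% and 17.0% in shoots. At an unadjusted p under 0.05 in limma, 347 introns were higher and 100 lower in roots, and 310 higher and 223 lower in shoots. All 37 root introns and all 28 higher shoot introns had no overlap between the 3 values of each genotype; among all tested introns 16.0% in roots and 12.3% in shoots had none, where chance gives 10%.

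The introns named by the rule were in genes without a symbol, and 4 of them passed in both tissues whichever single library was left out. The intron of GRMZM2G011636 at 1673715 to 1674087 on chromosome 3 (373 bp) had a retained share of 5.25% ± 1.17 (SD, n = 3) in wild-type roots and 89.7% ± 5.18 in rgh3 roots (limma adjusted p = 3.82e-05). Its shoot values were 5.91% ± 0.980 and 88.3% ± 0.446 (adjusted p = 5.98e-05). The intron of GRMZM2G022014 at 40378755 to 40379105 on chromosome 7 (351 bp) rose from 12.1% ± 2.08 to 89.6% ± 1.16 in roots (adjusted p = 0.000528). It rose from 9.23% ± 1.82 to 75.6% ± 13.4 in shoots (adjusted p = 0.00149). The intron of GRMZM2G359234 at 181707086 to 181707613 on chromosome 3 (528 bp) rose from 8.49% ± 1.55 to 82.3% ± 4.44 in roots (adjusted p = 0.000376). In shoots it went from 4.55% ± 1.81 to 67.4% ± 9.53 (adjusted p = 0.00096). The intron of GRMZM2G124617 at 45182806 to 45182945 on chromosome 6 (140 bp) rose from 6.16% ± 0.802 to 68.3% ± 10.5 in roots (adjusted p = 0.00413). The shoot share rose from 5.02% ± 1.73 to 74.1% ± 13.5 (adjusted p = 0.00239). In each of these 4 the 3 rgh3 values lay above the 3 wild-type values. With only the 2 groups compared, the shoot calls of GRMZM2G022014 (adjusted p = 0.148), GRMZM2G359234 (0.130) and GRMZM2G124617 (0.148) were lost.

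Other named introns also had large changes, and some rested on single libraries. The largest rise in shoots was that of GRMZM2G152436 at 63141888 to 63142011 on chromosome 8, from 7.06% ± 6.13 to 94.4% ± 9.78 (adjusted p = 0.0276). It was lost in 7 of the 12 fits without 1 library, with an adjusted p of up to 0.143, and its root values were 10.1% ± 10.98 and 84.4% ± 20.9 (adjusted p = 0.0712). In roots the intron of GRMZM2G065076 at 31612429 to 31612794 on chromosome 4 rose from 15.3% ± 9.02 to 92.7% ± 4.1 (adjusted p = 0.00688). That of GRMZM2G083620 at 899182 to 899257 on chromosome 5 rose in roots from 5.63% ± 6.59 to 79.9% ± 11.9 (adjusted p = 0.00676). Both root calls were kept without any single library, but the second was lost with only the 2 groups compared (adjusted p = 0.068). Both shoot calls (adjusted p = 0.0283 and 0.0411) were lost in 9 of the 12 fits. The intron of GRMZM2G159389 at 140346557 to 140346657 on chromosome 10 rose in roots from 22.3% ± 1.08 to 91.4% ± 13.4 (adjusted p = 0.0202), lost in 5 of the 12 fits with an adjusted p of up to 0.102.

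In other named introns the calls also differed in how far they rested on single libraries. In GRMZM2G098208 the intron at 95090541 to 95090809 on chromosome 1 rose from 8.51% ± 1.72 to 79.1% ± 9.13 in roots (adjusted p = 0.00112). In shoots the share rose from 13.1% ± 5.50 to 62.7% ± 8.35 (adjusted p = 0.0108). Its shoot call was lost without wild-type shoot replicate 2 (adjusted p = 0.0644) or 3 (0.0791). In GRMZM2G052178 the intron at 1287584 to 1287717 on chromosome 2 rose from 6.76% ± 2.13 to 76.7% ± 12.6 in roots (adjusted p = 0.003). In shoots it rose from 6.14% ± 1.93 to 64.3% ± 14.1 (adjusted p = 0.0108), a call lost without wild-type shoot replicate 1 (0.0541), 2 (0.0563) or 3 (0.0791). In GRMZM2G130432 the intron at 191482883 to 191482963 on chromosome 5 rose from 12.6% ± 11.7 to 97.1% ± 3.40 in shoots (adjusted p = 0.00288), a call kept without any single library but lost with only the 2 groups compared (0.146). Of all named introns, 9 of 12 root calls and 6 of 15 shoot calls were kept in every fit without 1 library, while 3 root calls and 13 shoot calls were lost with only the 2 groups. With replicate number as a block, the named shoot calls of GRMZM2G083620 at 898735 to 899108 (adjusted p = 0.0705) and 899182 to 899257 (0.115), of GRMZM2G159389 (0.104) and of GRMZM2G459811 (0.1002) were lost. In roots the block ended the calls of GRMZM2G083620 at 898735 to 899108 (adjusted p = 0.0948) and of GRMZM2G159389 (0.0864).

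Of the other genes with a symbol, 2 with introns among the calls are named here; they fall outside the naming rule, were chosen after their values were seen and were not followed through the fits without single libraries. The intron of krp1, which the table also calls KIN1, at 149284435 to 149284551 on chromosome 4 (GRMZM2G129569), rose from 0.000312% ± 0.00037 to 32.7% ± 2.21 in roots (adjusted p = 0.00804). In shoots the krp1 intron had 5.48% ± 4.33 in wild type and 2.68% ± 4.64 in rgh3 (adjusted p = 0.721), and the interaction had an unadjusted p = 7.87e-05 (adjusted p = 0.109). The intron of HIT2 (GRMZM2G126765) at 177643286 to 177643388 on chromosome 4 rose from 11.5% ± 4.00 to 53.1% ± 10.8 in roots (adjusted p = 0.0302). Its shoot values were 7.42% ± 3.79 and 40.7% ± 10.3 (adjusted p = 0.0674). In shoots 2 introns were lower in rgh3. One, in GRMZM2G118014 at 297048546 to 297048756 on chromosome 1, fell from 99.999% ± 0.00154 to 9.49e-05% ± 0.000162 (adjusted p = 0.00096). The other, in GRMZM2G459811 at 293793275 to 293793350 on chromosome 1, fell from 77.3% ± 6.86 to 29.8% ± 13.8 (adjusted p = 0.0283). Its call was lost in 10 of the 12 fits without 1 library, with an adjusted p of up to 0.158.

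**Figure D2:**
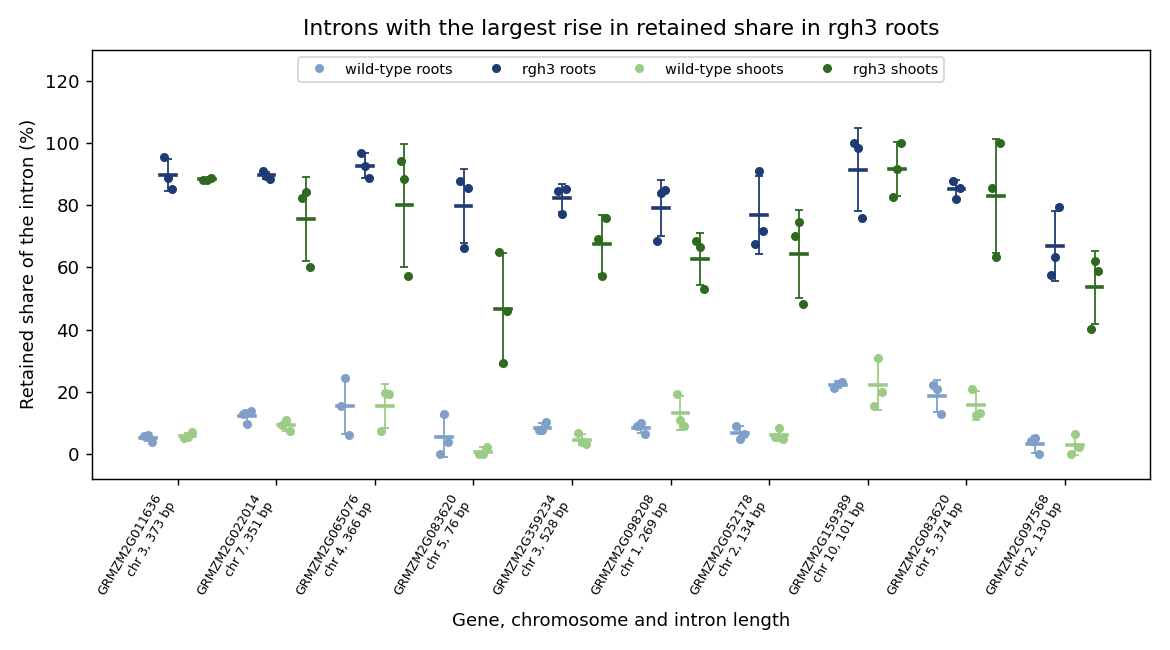
Points give the retained share in percent (vertical axis) in each library for 10 introns (horizontal axis). These introns had the largest rise in roots among those called there with no overlap between the genotypes. Values are shown for wild-type roots, rgh3 roots, wild-type shoots and rgh3 shoots, with a bar at the mean and error bars of 1 SD (n = 3). In GRMZM2G011636 the mean was 5.25% in wild-type roots and 89.7% in rgh3 roots, and 5.91% and 88.3% in shoots.

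The introns called higher were in part the same in both tissues. Of the introns with a higher share, 23 introns of 21 genes were called in both roots and shoots, where independent lists would share 0.149 (Fisher's exact test, two-sided, p = 6.73e-52). The lists are not independent, because the same fit gave both and root and shoot libraries of the same number are correlated. Some introns of the same gene also have equal shares. The p-value therefore does not show that the tissues repeat each other. Of the 42 introns of 37 genes called higher in either tissue, 39 had a higher mean share in rgh3 in both. The test of the difference between tissues in limma called 0 introns, with 284 at an unadjusted p under 0.05. How large a difference this test would find was not simulated for introns, so the 0 calls do not show that the tissues were alike. Averaged over tissues 66 introns changed, 62 higher and 4 lower. The number of root calls was 22 without wild-type root replicate 1, 22 without replicate 2, 21 without replicate 3, 21 without rgh3 root replicate 1 and 79 without rgh3 shoot replicate 3. The number of shoot calls was 19 without wild-type root replicate 1, 19, 10 and 10 without wild-type shoot replicates 1, 2 and 3, and 3 when only the 2 shoot groups were fitted.

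Isoform usage changed in 58 transcripts of 38 genes in roots (28 higher, 30 lower) and in 31 transcripts of 23 genes in shoots (14 higher, 17 lower). The shares of a gene sum to a fixed total, so the higher and lower counts are not independent. Some calls also repeat intron calls. In roots T02 of GRMZM2G359234 and the called intron of that gene both went from 8.49% to 82.3%. SDG123 (GRMZM2G080462), a SET domain gene on chromosome 1, had transcript T01 at 84.9% ± 3.96 of its FPKM in wild-type roots and 0.0171% ± 0.0156 in rgh3 roots (limma adjusted p = 0.00301). In shoots that share fell from 83.5% ± 6.13 to 7.35% ± 12.7 (adjusted p = 0.00742; 0.0574 without wild-type shoot replicate 3). In lon1 (GRMZM2G109560), a gene for a Lon protease on chromosome 7, the share of T02 rose from 7.18% ± 2.94 to 62.8% ± 1.73 in roots (adjusted p = 0.00612). The shoot share of T02 rose from 8.11% ± 4.60 to 63.9% ± 2.19 (adjusted p = 0.00577). In GRMZM2G103152 the share of T04 fell from 79.7% ± 9.62 to 5.71% ± 8.58 in roots (adjusted p = 0.00689, and 0.0707 with only the 2 groups compared). In shoots it fell from 88.8% ± 3.20 to 1.60% ± 1.98 (adjusted p = 0.00245). The rgh3 and wild-type values of these transcripts did not overlap in either tissue. Averaged over tissues 116 transcripts changed, and the difference between tissues was called for 0 in limma, with 618 at an unadjusted p under 0.05.

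The root isoform count was 19 without wild-type root replicate 1, 21 without replicate 2, 19 without replicate 3, 21 and 32 without rgh3 root replicates 1 and 2, and 140 without rgh3 shoot replicate 3. In shoots it was 18 and 18 without wild-type root replicates 1 and 2, 19 and 15 without wild-type shoot replicates 1 and 3, 20 without rgh3 root replicate 2 and 59 without rgh3 shoot replicate 3. With a replicate block the shoot count was 17 (8 higher, 9 lower), and with only the 2 shoot groups it was 0. The blocked root fit lost T01 of GRMZM2G083620 (adjusted p = 0.0965), T02 of GRMZM2G130432 (0.0543), T03 of GRMZM2G170382 (0.0705) and T04 of GRMZM5G841900 (0.1201). The blocked shoot fit lost T01 of GRMZM2G007195 (adjusted p = 0.0669), T01 and T02 of GRMZM2G052178 (both 0.0608), T01 of GRMZM2G083620 (0.0957), T03 of GRMZM2G133028 (0.0795) and T01 of GRMZM2G152436 (0.110).

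In roots, genes for a laccase, a chitinase, a diterpene synthase and a potassium transporter were higher in rgh3, and genes for a lipoxygenase and an aquaporin were lower. Laccase lac3 (GRMZM2G169033), at 181527348 to 181530838 on chromosome 4, rose from 1.23 ± 0.449 FPKM (SD, n = 3) to 166 ± 191 (log2 6.16, SE 0.85, limma adjusted p = 0.00519). Chitinase chiA (GRMZM2G051943), at 33534101 to 33535449 on chromosome 2, rose from 10.9 ± 4.8 to 429 ± 370 (log2 5.04, SE 0.78, adjusted p = 0.008). The ent-copalyl diphosphate synthase an2 (GRMZM2G044481), at 79703253 to 79707015 on chromosome 1, rose from 3.93 ± 0.998 to 145 ± 124.1 (log2 4.73, SE 0.65, adjusted p = 0.00519). The potassium transporter HAK5 (GRMZM2G084779) rose from 1.61 ± 0.882 to 88.2 ± 90.6 (log2 4.85, SE 0.82, adjusted p = 0.0106). The lipoxygenase lox11 (GRMZM2G009479) fell from 207 ± 91.9 to 14.8 ± 10.1 (log2 -3.94, SE 0.50, adjusted p = 0.00335). The aquaporin NIP1-1 (GRMZM2G041980) fell from 59.9 ± 26.3 to 4.31 ± 2.54 (log2 -3.85, SE 0.46, adjusted p = 0.00288). In each named gene the 3 rgh3 values lay on one side of the 3 wild-type values, and these 6 calls were kept without any single library. With only the 2 groups compared, those of HAK5 (adjusted p = 0.095) and NIP1-1 (0.0531) were lost.

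Altogether 960 of 25714 genes changed in roots, 438 higher and 522 lower, and 4625 had an unadjusted p under 0.05. The higher genes outnumbered the lower with equal sums (559 and 458) and without wild-type root replicates 1 (134 and 132), 2 (120 and 116) and 3 (272 and 173) or rgh3 root replicate 3 (360 and 339). Without rgh3 root replicate 2 the numbers were 231 and 513. The alternative oxidase aox3 (GRMZM2G074743) was listed at 0, 0 and 0.161 FPKM in wild-type roots and had 16.5, 5.51 and 3.88 in rgh3 roots (adjusted p = 0.00747). The peroxidase PER66 (GRMZM2G133475) had 66.9, 49.5 and 175 in wild-type roots and 0, 3.57 and 0.449 in rgh3 roots (adjusted p = 0.008). The homeobox gene HB34 (GRMZM2G002915) had 9.81, 11.8 and 6.93 and then 0, 0.202 and 0 (adjusted p = 0.00219). The heat shock factor binding protein gene hsbp1 (GRMZM2G085924) fell from 669 ± 186 to 41.3 ± 28.4 (log2 -4.28, SE 0.62, adjusted p = 0.00637). The sesquiterpene synthase model tps6/tps11 (GRMZM2G127087) rose from 1.07 ± 0.562 to 385 ± 347 (log2 7.29, SE 1.28, adjusted p = 0.012). It was not called without wild-type root replicate 1 (0.0569), rgh3 root replicate 1 (0.063) or wild-type root replicate 2 (0.0506). The thaumatin-like PR-5 (GRMZM2G402631) rose from 2.83 ± 1.19 to 395 ± 531 (log2 5.79, adjusted p = 0.013), but not without wild-type root replicate 1 (0.0593) or 2 (0.0506). With only the 2 groups compared, the calls of PER66 (adjusted p = 0.0539), tps6/tps11 (0.0665) and PR-5 (0.0936) were lost. The number of called genes was 266, 236 and 445 without wild-type root replicates 1, 2 and 3, and 221 without rgh3 root replicate 1. It was 636 without wild-type shoot replicate 1 and 1775 without rgh3 shoot replicate 3, a library that entered the root comparison through the filter and the estimate of the spread. All 960 genes were among those 1775.

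Of the 36 gene lists, 10 differed in roots by camera with the preset correlation, and 0 did with an estimated correlation. Pathogenesis-related and protease inhibitor genes were higher, with 7 of 20 members up and 0 down (11 and 0 adjusted over the list alone), a median log2 of 1.85 and an adjusted p of 4.06e-06. For this list the adjusted p = 0.705 with an estimated correlation. Among them wip1 (GRMZM2G156632) rose from 15.5 ± 6.25 to 71.9 ± 6.60 (adjusted p = 0.0252). The call was lost without wild-type root replicates 1 (0.1) and 2 (0.0786) and rgh3 root replicates 1 (0.102), 2 (0.0564) and 3 (0.0526). Aquaporins were lower, with 1 of 27 members up and 5 down (1 and 11 adjusted over the list alone), median log2 -1.45, adjusted p = 8.89e-06. For aquaporins the adjusted p = 0.705 with an estimated correlation. The plasma membrane aquaporin pip2-5 (GRMZM2G178693) fell from 699 ± 357 to 76.8 ± 29.7 (log2 -3.16, adjusted p = 0.0162). This call was lost without wild-type root replicate 1 (0.0749), rgh3 root replicate 1 (0.0818) or wild-type root replicate 2 (0.0551). The list of root genes was lower, with 0 of 23 up and 2 down (0 and 9 adjusted over the list alone), median log2 -1.84, adjusted p = 8.89e-06. For root genes the adjusted p = 0.705 with an estimated correlation. Its 2 members that fell were zrp4 (GRMZM2G017557, 320 ± 153 to 37.6 ± 40.1, adjusted p = 0.0279) and the phosphate transporter pht7 (GRMZM2G112377, 5.23 ± 2.68 to 0.688 ± 0.636, adjusted p = 0.0326). The zrp4 call was lost without wild-type root replicates 1 (0.104) and 2 (0.107) and rgh3 root replicates 1 (0.113) and 3 (0.0782). The pht7 call was lost in 8 of the 12 fits without 1 library, with an adjusted p of up to 0.139. Without rgh3 root replicate 3 the number of lists called was 4.

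Abscisic acid and dehydration genes were lower in roots, with 0 of 46 up and 6 down (0 and 6 adjusted over the list alone), median log2 -0.36, adjusted p = 0.0311. It had an adjusted p = 0.705 with an estimated correlation. The kinase SnRK2.5 (GRMZM2G110908) fell from 80.3 ± 19.4 to 30.8 ± 6.17 (adjusted p = 0.011), lost without rgh3 root replicate 1 (0.0542) and wild-type root replicate 2 (0.052). Histones were lower, with 0 of 14 up and 1 down (0 and 6 adjusted over the list alone), median log2 -0.88, adjusted p = 0.000352. Histones had an adjusted p = 0.767 with an estimated correlation. Expansins and cell wall genes had 1 of 61 up and 2 down (1 and 3 adjusted over the list alone), median log2 -0.57, adjusted p = 0.0056. The cell wall list had an adjusted p = 0.895 with an estimated correlation. Peroxidases and oxidant scavenging had 0 of 23 up and 1 down (0 and 2 adjusted over the list alone), median log2 -0.33, adjusted p = 0.0311. Peroxidases had an adjusted p = 0.767 with an estimated correlation. Housekeeping genes had 0 of 28 called by limma (0 adjusted over the list alone, 1 higher and 7 lower at an unadjusted p under 0.05), median log2 -0.44, adjusted p = 0.0311. Housekeeping genes had an adjusted p = 0.946 with an estimated correlation. NAC factors were higher, with 1 of 25 up and 0 down (2 and 0 adjusted over the list alone), median log2 0.59, adjusted p = 0.0363. NAC factors had an adjusted p = 0.767 with an estimated correlation. Potassium transporters had 1 of 21 up, HAK5, and 2 down (1 and 6 adjusted over the list alone), median log2 -0.49, adjusted p = 0.0463. Potassium transporters had an adjusted p = 0.812 with an estimated correlation. The NAC and potassium transporter lists were added after the gene symbols were seen and before any group comparison. Quantile scaling ended the calls of the NAC, abscisic acid, housekeeping and peroxidase lists (adjusted p = 0.0559, 0.064, 0.099 and 0.064). Equal sums ended that of the NAC list (0.0567). No scaling turned the direction of a called root list.

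In terpene synthases 3 of 8 members rose in roots and 0 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0617). They were an2, tps6/tps11 and the kaurene synthase-like KSL4 (GRMZM2G016922), which went from 0.583 ± 0.259 to 16.9 ± 11.1 (log2 4.06, adjusted p = 0.0111; 0.0551 without wild-type root replicate 1). WRKY factors had 3 of 16 up in roots (4 up and 1 down adjusted over the list alone). Oxylipins and jasmonate had 2 of 42 up and 2 down (2 and 2 adjusted over the list alone), and cytokinin 1 of 29 up and 3 down (1 and 4). Counts up and down in roots were 0 and 1 of 45 for auxin (0 and 0 adjusted over the list alone) and 1 and 0 of 12 for benzoxazinoid synthesis (1 and 0). They were 0 and 1 of 42 for bHLH factors (0 and 1), 1 and 0 of 32 for bZIP factors (1 and 0), and 1 and 0 of 17 for the C4 and Calvin cycle (1 and 0). The counts were 0 and 2 of 32 for cell cycle and DNA replication (0 and 3), 0 and 1 of 63 for chromatin factors (0 and 1) and 1 and 0 of 34 for glutathione S-transferases (1 and 0). Further counts were 0 and 2 of 31 for homeobox factors (0 and 4), 0 and 1 of 26 for MADS and flowering genes (1 and 2), and 0 and 2 of 48 for MYB factors (0 and 2). In the other 11 lists limma called 0 members over all genes. At an unadjusted p under 0.05, 1 and 0 of 16 anaerobic response genes, 1 and 2 of 14 autophagy genes and 0 and 1 of 27 endoplasmic reticulum folding genes were up and down. The counts on these terms were 2 and 1 of 30 EREB factors, 3 and 1 of 17 flavonoid pathway genes, 1 and 0 of 28 heat shock proteins and 1 and 1 of 18 light reaction genes. Ribosomal proteins had 0 and 0 of 38, splicing factors 2 and 0 of 18, sucrose and starch 4 and 2 of 33, and seed tissue markers 2 and 0 of 5. Adjusted over the list alone, 2 members of each of the last 2 lists were higher and 0 of the others were called. Camera called none of the lists in this paragraph in roots, with adjusted p-values from 0.0585 to 0.978. The medians and means of the MADS and sucrose and starch lists differed in sign.

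In shoots, photosynthesis genes were lower in rgh3 and pathogenesis-related and WRKY genes were higher. The light reaction list had 0 of 18 members up and 6 down (0 and 14 adjusted over the list alone), with a median log2 of -1.77, camera adjusted p = 4.61e-09. Light reaction genes had an adjusted p = 0.273 with an estimated correlation. The C4 and Calvin cycle list had 1 of 17 up and 9 down (2 and 9 adjusted over the list alone), median log2 -1.66, adjusted p = 0.00866. C4 and Calvin cycle genes had an adjusted p = 0.518 with an estimated correlation. The glyceraldehyde phosphate dehydrogenase gene gpa1 (GRMZM2G337113) fell from 2475 ± 733 FPKM (SD, n = 3) to 490.1 ± 42.3 (log2 -2.30, SE 0.36, adjusted p = 0.00662). The ferredoxin-thioredoxin reductase gene ftr1 (GRMZM2G122793) fell from 327 ± 89.99 to 112 ± 23.5 (log2 -1.53, SE 0.24, adjusted p = 0.00685). The Rubisco small subunit gene rbcS (GRMZM2G098520) fell from 2525 ± 708 to 807 ± 263 (log2 -1.66, adjusted p = 0.0109; 0.0596 without wild-type shoot replicate 3). The member that rose was pck2 (GRMZM5G870932), a phosphoenolpyruvate carboxykinase gene, from 14.4 ± 4.8 to 65.7 ± 21.0 (log2 2.18, SE 0.36, adjusted p = 0.00768). With only the 2 groups compared, the calls of gpa1 (adjusted p = 0.0536), ftr1 (0.0621) and rbcS (0.176) were lost. In each named gene the 3 rgh3 values lay on one side of the 3 wild-type values.

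Pathogenesis-related and protease inhibitor genes had 5 of 20 up and 0 down in shoots (11 and 0 adjusted over the list alone), median log2 1.78, adjusted p = 4.61e-09. Here the adjusted p = 0.389 with an estimated correlation. PR10 (GRMZM2G112524) rose from 10.0 ± 0.918 to 162 ± 71.9 (log2 3.89, SE 0.54, adjusted p = 0.00456). The cystatin gene cpi2 (GRMZM2G012160) rose from 207 ± 31.6 to 1280.2 ± 768 (log2 2.48, adjusted p = 0.0166), but not without wild-type shoot replicate 1 (0.061), 2 (0.0624) or 3 (0.0601). WRKY factors had 5 of 16 up and 0 down (5 and 0 adjusted over the list alone), median log2 0.30 and mean log2 0.78, adjusted p = 0.000109. WRKY factors had an adjusted p = 0.0801 with an estimated correlation. WRKY42 (GRMZM5G812272) rose from 2.02 ± 1.21 to 12.5 ± 2.71 (log2 2.59, SE 0.39, adjusted p = 0.0061). WRKY43 (GRMZM2G148087) rose from 0.437 ± 0.230 to 4.40 ± 1.15 (log2 2.79, adjusted p = 0.00735). WRKY29 (GRMZM2G040298) rose from 0.716 ± 0.116 to 4.21 ± 1.29 (log2 2.17, adjusted p = 0.00767). These 3 calls were kept without any single library, but with only the 2 groups compared those of WRKY42 (adjusted p = 0.059) and WRKY29 (0.0629) were lost. Glutathione S-transferases had 3 of 34 up and 1 down (5 and 1 adjusted over the list alone), median log2 0.91, adjusted p = 0.00866. Glutathione S-transferases had an adjusted p = 0.636 with an estimated correlation. Among them gst23 (GRMZM2G416632) rose from 6.45 ± 3.14 to 51.7 ± 16.4 (log2 3.02, SE 0.51, adjusted p = 0.00881). Ribosomal proteins had 0 of 38 up and 2 down (0 and 2 adjusted over the list alone), median log2 -0.44, adjusted p = 0.00869. Ribosomal proteins had an adjusted p = 0.950 with an estimated correlation. The lower members were rpl19 (GRMZM2G171444, 819 ± 229 to 219 ± 70.1, adjusted p = 0.00464) and rpl29 (GRMZM2G028216, 442 ± 115 to 144 ± 39.3, adjusted p = 0.0178). The rpl29 call was lost without wild-type shoot replicates 1 (0.0516) and 3 (0.0894) and rgh3 shoot replicate 1 (0.0583). Factors of the bZIP family had 2 of 32 up and 0 down (5 and 2 adjusted over the list alone), median log2 0.20, adjusted p = 0.032. The bZIP list had an adjusted p = 0.612 with an estimated correlation. The WRKY and bZIP lists were likewise added after the symbols were seen.

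**Figure D3:**
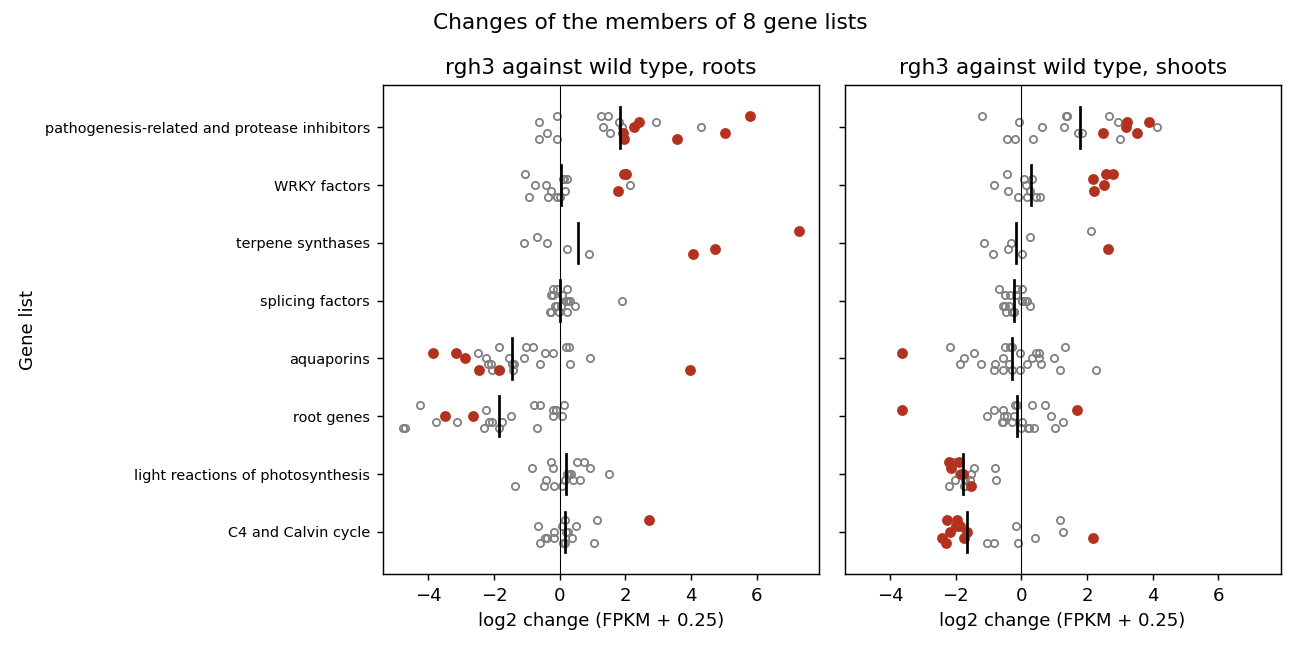
Each point is the log2 change (rgh3 against wild type, horizontal axis) of 1 tested gene of 8 lists (vertical axis), with roots and shoots in separate panels; filled red points had an adjusted p under 0.05, open grey points did not, and the black line is the list's median. In shoots the medians were 1.78 for pathogenesis-related and protease inhibitor genes and -1.77 for light reaction genes, and in roots -1.45 for aquaporins.

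Altogether 1130 genes changed in shoots, 363 higher and 767 lower, and 4583 had an unadjusted p under 0.05. The NAC factor NAC12/NAC126 (GRMZM2G018436) rose from 0.879 ± 0.616 to 24.7 ± 10.7 (log2 4.55, SE 0.51, adjusted p = 0.00238). GB1 (GRMZM2G062531) rose from 4.86 ± 2.29 to 98.6 ± 83.7 (log2 3.95, SE 0.68, adjusted p = 0.00892). The nitrate reductase gene NNR1 (GRMZM2G568636) fell from 47.6 ± 6.64 to 7.95 ± 2.03 (log2 -2.57, SE 0.41, adjusted p = 0.00724). The O-methyltransferase gene pOMT1 (GRMZM2G383088) fell from 481 ± 122 to 81.6 ± 16.3 (log2 -2.54, SE 0.33, adjusted p = 0.00312), and the superoxide dismutase gene sodC (GRMZM2G106928) from 509 ± 114 to 121 ± 27.3 (log2 -2.07, SE 0.25, adjusted p = 0.00245). These 5 calls were kept without any single library, and with only the 2 groups compared that of GB1 was lost (adjusted p = 0.0631). The dehydroascorbate reductase gene dhar4 (GRMZM5G826194) fell from 46.1 ± 3.03 to 6.12 ± 2.23 (log2 -2.92, adjusted p = 0.0123; 0.0634 without wild-type shoot replicate 3). The phytoene synthase gene psy2 (GRMZM2G149317) fell from 39.2 ± 15.6 to 6.51 ± 4.31 (log2 -2.81, adjusted p = 0.0291), but not without wild-type shoot replicate 1 (0.113), 2 (0.0687) or 3 (0.1).

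The split between higher and lower shoot genes moved with the scaling. It was 32.1% higher as deposited and 47.8% (498 higher, 543 lower) with quantile scaling. It was 64.3% (696 and 387) with libraries scaled to an equal sum, and 46.4% (445 and 515) without rgh3 shoot replicate 3. The median log2 change of all genes was -0.16 as deposited, 0.02 with quantile scaling and 0.15 with equal sums, so directions of single genes and lists are best read against it. Pathogenesis-related, WRKY, light reaction and C4 lists kept their direction and their call under each scaling. The glutathione S-transferase call ended with equal sums (adjusted p = 0.0878). The bZIP call ended with equal sums and with quantile scaling (0.0848 and 0.159) and without rgh3 shoot replicate 3 (0.126). The ribosomal call ended with equal sums and with quantile scaling (0.0784 and 0.954). The number of called genes was 534, 489 and 301 without wild-type shoot replicates 1, 2 and 3 and 719 without rgh3 shoot replicate 1. Without rgh3 shoot replicate 3 it was 960, of which 725 were among the 1130. The number of lists called was 3 without rgh3 shoot replicate 1.

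In the other lists the counts of members up and down in shoots were 0 and 1 of 27 for aquaporins (1 and 1 adjusted over the list alone), 1 and 0 of 42 for bHLH factors (0 and 0) and 0 and 1 of 29 for cytokinin (0 and 1). The counts were 0 and 2 of 5 for seed tissue markers (0 and 3), and 1 and 1 of 61 for expansins and cell wall (1 and 1). Further counts were 0 and 1 of 31 for homeobox factors (0 and 1), 0 and 2 of 48 for MYB factors (0 and 2) and 1 and 0 of 25 for NAC factors (1 and 0). They were 1 and 0 of 42 for oxylipins and jasmonate (1 and 0), 1 and 4 of 23 for peroxidases and oxidant scavenging (2 and 5). The remaining counts were 1 and 0 of 21 for potassium transporters (1 and 2), 1 and 1 of 23 for root genes (1 and 1) and 1 and 0 of 8 for terpene synthases (1 and 0). In 16 lists limma called 0 members, both over all genes and adjusted over the list alone. At an unadjusted p under 0.05 their counts were, for abscisic acid, 7 up and 4 down of 46 tested. On the same terms 1 and 1 of 16 anaerobic response, 0 and 1 of 14 autophagy, 1 and 2 of 45 auxin and 0 and 1 of 12 benzoxazinoid genes were up and down. So were 0 and 1 of 32 cell cycle genes, 0 and 2 of 63 chromatin factors, 3 and 0 of 27 folding genes and 2 and 2 of 30 EREB factors. The flavonoid pathway had 1 and 0 of 17, heat shock proteins 0 and 1 of 28, histones 0 and 0 of 14 and housekeeping genes 2 and 3 of 28. MADS and flowering genes had 1 and 0 of 26, splicing factors 0 and 2 of 18, and sucrose and starch 0 and 2 of 33. Camera called none of the lists in this paragraph in shoots, with adjusted p-values from 0.0842 to 0.890. Camera sets the t statistics of a list against those of all other genes. The lists of autophagy, endoplasmic reticulum folding, expansins, MADS, potassium transporter and root genes had a negative median with a test direction upwards, and the medians and means of the bHLH, flavonoid, oxylipin and terpene synthase lists differed in sign.

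Among the genes that rose in both tissues were HAK5, TIFY2/TIFY3 and aox3. HAK5 rose in shoots from 1.37 ± 0.441 to 25.7 ± 5.10 (log2 4.03, adjusted p = 0.0187), lost without wild-type shoot replicate 1 (0.0554), 2 (0.0515) or 3 (0.0861) or rgh3 shoot replicate 1 (0.0527). The jasmonate-type repressor gene TIFY2/TIFY3 (GRMZM5G838098) rose from 0.683 ± 0.463 to 17.0 ± 8.99 in roots (log2 4.19, SE 0.47, adjusted p = 0.00219). In shoots TIFY2/TIFY3 rose from 2.18 ± 0.461 to 10.8 ± 1.82 (log2 2.19, adjusted p = 0.0237). The shoot call was lost without wild-type shoot replicates 1 (0.057), 2 (0.0887) and 3 (0.0852) and rgh3 shoot replicates 2 (0.057) and 3 (0.0512). Alternative oxidase aox3 was listed at 0 in the 3 wild-type shoot libraries and had 7.82, 1.32 and 5.47 in rgh3 shoots (adjusted p = 0.00938). These genes with a symbol were chosen after their values were seen. The 10 with the largest mean change under the rule have no symbol, and all rose. Among those, GRMZM2G388045 rose from 4.34 ± 1.68 to 159.5 ± 90.7 in roots (log2 4.95, adjusted p = 0.00219). In shoots it rose from 0.778 ± 0.193 to 59.9 ± 29.4 (log2 5.74, adjusted p = 0.00111). The other 9 had log2 changes of 5.36 to 7.33 in roots and 4.92 to 7.72 in shoots. Of the 10, 8 root calls and 7 shoot calls were kept in every fit without 1 library. With only the 2 groups compared, 5 root calls and 2 shoot calls were lost. In all, 149 genes were higher in both tissues, where independent lists would share 6.18 (Fisher's exact test, two-sided, p = 3.35e-172), and 60 were lower in both, against 15.6 (p = 3.42e-19). Another 8 genes were called in opposite directions. The root and shoot lists are not independent, because the same fit gave both and root and shoot libraries of the same number are correlated. These p-values of Fisher's exact test therefore do not show that the tissues repeat each other. Across genes, which are not independent replicates, the root and shoot log2 changes had Pearson's r of 0.397 and Spearman's rho of 0.351.

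The interaction asks whether the mutant's effect differed between shoots and roots, and 76 genes passed, 19 with a positive and 57 with a negative difference of the log2 change in shoots minus that in roots, with 2712 at an unadjusted p under 0.05. The lipoxygenase lox1 (GRMZM2G156861) fell in roots from 1269 ± 308 to 154 ± 43.5 (adjusted p = 0.0139). In shoots lox1 had 136 ± 69.8 and 410.3 ± 251 (adjusted p = 0.186), an interaction of log2 4.47 (SE 0.78, adjusted p = 0.0437). Its root call was lost without wild-type root replicate 1 (0.0589) or 2 (0.0631) or rgh3 root replicate 1 (0.063). The pyruvate phosphate dikinase gene pdk1 (GRMZM2G306345) rose in roots from 31.8 ± 16.8 to 243 ± 202 (adjusted p = 0.0209). It fell in shoots from 10519 ± 2716 to 2145 ± 502 (adjusted p = 0.0359), an interaction of log2 -5.00 (SE 0.77, adjusted p = 0.0352). Its root call was lost without wild-type root replicate 2 (0.0836) or 3 (0.0828) or rgh3 root replicate 1 (0.0708). NIP1-1, which fell in roots, had 122 ± 10.7 in wild-type and 121 ± 27.2 in rgh3 shoots (interaction log2 3.82, adjusted p = 0.0436). TSA (GRMZM5G841619), a tryptophan synthase alpha subunit gene, rose in roots from 24.7 ± 4.07 to 68.4 ± 8.26 (adjusted p = 0.0119). In shoots TSA had 50.1 ± 10.1 and 30.4 ± 9.01 (adjusted p = 0.138), an interaction of log2 -2.21 (adjusted p = 0.0425). Its root call was lost without wild-type root replicate 2 (0.0583) or rgh3 root replicate 1 (0.0617). Each named interaction call was lost in at least 10 of the 12 fits without 1 library, with an adjusted p of up to 0.147. The number of interaction calls was 1, 2 and 5 without wild-type root replicates 1, 2 and 3, and 4, 4 and 1 without wild-type shoot replicates 1, 2 and 3. It was 6 and 6 without rgh3 root replicates 1 and 3, and 3 and 5 without rgh3 shoot replicates 1 and 2. With quantile scaling it was 45, with 20 positive and 25 negative, a share of 44.4% positive against 19 of 76 as deposited, and with a replicate block 139 (37 and 102).

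Averaged over both tissues 2315 genes changed, 1034 higher and 1281 lower. The share that was higher, 44.7%, was 55.1% (1591 and 1298) with quantile scaling and 71.9% (1953 and 763) with equal sums. More were higher than lower also without rgh3 shoot replicate 3 (1517 and 1279), wild-type root replicate 3 (821 and 771) or wild-type shoot replicate 2 (670 and 659), and among genes with a fold of 2 or more (872 and 844). The count was 1369 and 1501 without wild-type root replicates 1 and 2, 1349, 1329 and 1376 without wild-type shoot replicates 1, 2 and 3, and 1401 without rgh3 root replicate 1.

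The tissues themselves differed most, and gene groups of each organ were where their names place them. In wild type 6294 genes differed, 3010 higher in roots and 3284 higher in shoots. With median ratio scaling the numbers were 2578 and 3746, but more were higher in roots with quantile scaling (3868 and 3422), with equal sums (3998 and 3189), with array weights (5004 and 4037), with only the 2 groups (3978 and 3786) and without rgh3 shoot replicate 3 (4001 and 3757). Phosphoenolpyruvate carboxylase pep1 (GRMZM2G083841) had 6.10 ± 1.88 FPKM in roots and 5088 ± 1438 in shoots (log2 -9.65, SE 0.45, adjusted p = 4.28e-08). The gene cp29 (GRMZM2G033885), for a chlorophyll-binding antenna protein, had 1.42 ± 0.769 and 1464 ± 552 (log2 -9.79, adjusted p = 1.12e-07). The peroxidase PER2 (GRMZM2G040638) had 349 ± 118 in roots and 0.526 ± 0.624 in shoots (log2 9.03, adjusted p = 3.13e-06). The tonoplast aquaporin TIP2-2 (GRMZM2G056908) had 831 ± 198 and 3.99 ± 3.22 (log2 7.84, adjusted p = 1.18e-06). All 18 light reaction genes were lower in roots (median log2 -8.49, camera adjusted p = 1.63e-23, and adjusted p = 0.0362 with an estimated correlation). Of the C4 and Calvin cycle genes 11 of 17 were lower and 3 higher in roots (median log2 -7.36, adjusted p = 4.32e-07, and adjusted p = 0.101 with an estimated correlation). Of 23 root genes 15 were higher and 1 lower (17 and 1 adjusted over the list alone; median log2 2.84, adjusted p = 0.000263, and adjusted p = 0.560 with an estimated correlation). All 12 named tissue genes were kept without any single library. In rgh3 4543 genes differed between tissues, 2058 higher and 2485 lower in roots, and the share that was higher, 45.3%, was 32.2% (1488 and 3129) with median ratio scaling and 53.6% (2574 and 2228) without rgh3 shoot replicate 1.

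Called genes were tested for clustering by chromosome with Fisher's exact test, since mutants and siblings of a segregating family can differ by a linked stretch of chromosome. In roots 0 of 10 chromosomes passed after adjustment and 1, chromosome 3, had an unadjusted p under 0.05 (adjusted p = 0.0597). In shoots 0 passed and 0 had an unadjusted p under 0.05. On chromosome 5, which holds the Rgh3 models, 3.14% of tested genes were called in roots against 3.81% elsewhere (adjusted p = 0.298). In shoots the shares were 4.58% and 4.37% (adjusted p = 0.756). Averaged over tissues, 10.7% of the tested genes on chromosome 3 were called, against 8.80% of those elsewhere (adjusted p = 0.0127).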

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

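The tests of retention in introns of all genes and in the same introns of the other tissue were chosen after the results they measure had been seen, as were scaling to an equal sum and the count of splits that keep the pairs. The other tests here were set down after the calls but before the result each one measures was seen.

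A difference between tissues drew attention in 76 genes whose interaction of genotype and tissue passed in limma. Among the named genes, the log2 change in shoots minus that in roots was 4.47 for lox1 and 3.82 for NIP1-1, which fell in roots. It was -5.00 for pdk1, -3.07 for PYG7, -2.27 for EMB2756, -2.25 for rpl19 and -2.21 for TSA. PYG7 (GRMZM5G809292) fell in shoots from 172 ± 39.0 to 45.5 ± 13.5 FPKM (adjusted p = 0.00735), and EMB2756 (GRMZM2G043212) from 491 ± 171 to 121 ± 9.96 (adjusted p = 0.00464). Of 100 splits of the libraries that exchanged genotypes within a tissue, 3 gave as many interaction calls, the real one included. The highest other split gave 2315, because exchanging the genotypes in 1 tissue turns the interaction into the average comparison. These splits separate libraries that same numbers pair. Only 4 splits part all shoot pairs and keep the root and shoot libraries of a number together, too few for a share under 0.05. Among them the real one gave 76 and the highest other 0. The others of these splits mix the genotypes within groups, which lowers their counts where the genotypes differ. Leaving out 1 library gave 1 to 79 calls.

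Introns with a higher retained share in rgh3 were the pattern closest to the mutated gene. Unspliced RNA or genomic DNA in the rgh3 libraries would raise introns generally. Those not called moved by at most 2.37% of the median change of the called ones. The other tested introns of the same genes (22 in roots, 19 in shoots) moved by at most 2.04%. Both sets leave out called introns, which lowers these percentages by construction. Over all tested introns the median change was 1.05 points in roots, where 60.8% were higher in rgh3, and 0.226 in shoots. A general rise as large as the called changes was thus not seen, but a small one is not excluded. The median change of the shoot introns was 47.2 points without rgh3 shoot replicate 3 against 48.3 with it, so its size did not rest on the shallow library. These introns were chosen with that library included, so the medians do not show whether it shaped which introns were called. Without it, 24 of the 27 calls of named introns in roots or shoots were kept. Of the 37 introns called higher in roots, 35 (94.6%) had a higher mean share in rgh3 shoots, as had 52.7% of all tested introns. Root and shoot libraries of the same number are correlated in both genotypes, so the shoots are no independent test of the root introns, and this share decides nothing. An effect of the genotype on particular introns stays open as a hypothesis found on the same libraries; whether the introns share a splice site type is not analysed here.

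Lower light reaction and C4 genes in rgh3 shoots had a median log2 of -1.74 over 35 members. Without the shallow library the median was -1.41, and over 3 other scalings it came closest to 0 at -1.30, so neither accounts for it. Root tissue in the shoot samples would have to make up 70.04% of the RNA, but 99 genes found almost only in roots stood in rgh3 shoots at a median of 1.64% of their level in rgh3 roots, with an upper quartile of 5.95%. In wild type that median was 0.253%, but the genes were chosen for a low ratio there, and the rgh3 ratio is taken over rgh3 roots. The medians therefore do not show whether these genes were higher in rgh3 shoots. A small share of root tissue, far below the one needed, is not excluded. A difference in developmental stage or in greening between mutant and sibling seedlings was not tested and stays open beside a direct effect of the genotype.

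Higher pathogenesis-related and protease inhibitor genes in rgh3 appeared in both tissues. In shoots the median log2 change was 1.78, and 2.17 without the shallow library. Over 3 other scalings the lowest median was 1.89 in shoots and 1.82 in roots, the latter against 1.85 as deposited, so neither accounts for it. Infection or wounding of the mutant seedlings, or a response of the plants to the mutation, was not tested and stays open.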

How the results depend on the processing

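Over all alternatives, 4558 values belonged to single named genes, introns or transcripts called as reported. Of these 3600 stayed called in the same direction, 958 (21.02%) were no longer called and 0 reversed. The fit of only the 2 groups compared ended 81 of 144 named gene calls, 16 of 27 intron calls and 27 of 47 isoform calls. Among the 10 genes named for each direction, it ended 6 calls of rises and 5 of falls in roots, and 5 of rises and 7 of falls in shoots. Of 4477 values of results not called as reported, 221 became called. Of the counts 174 stayed within 1.5 times the reported one and 74 did not. Scaling to an equal sum was added after the data were seen. The comparison of U12-type introns was not run. Where no cause is given below, the cause was not tested.

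With only the 2 groups compared, the counts were 307 genes in roots (183 of them higher) and 536 in shoots (140, 396). Between tissues the count was 2573 in rgh3 (856, 1717), but it rose to 7764 in wild type (3978, 3786). In shoots 3 introns (2, 1) and 0 isoforms were called. This fit has fewer samples and takes the spread from those 2 groups alone. Which of these moved the counts was not tested. Array weights gave 1499 genes in roots (709, 790), 2110 in shoots (899, 1211), 3548 averaged over tissues and 234 for the interaction (76, 158); the weight of rgh3 shoot replicate 3 was 0.169. The interaction gave 198 genes with a pseudocount of 1 (48, 150), 26 with 0.05 (6, 20), 127 with median ratio scaling (30, 97), 45 with quantile scaling (20, 25) and 139 with a replicate block (37, 102). diffSplice on log2 FPKM gave 117 transcripts in roots (57, 60) and 97 in shoots (47, 50), and the block gave 17 isoforms in shoots. Beyond the interaction count, that isoform count and the calls named in the report, the block changed no other count by more than 1.5 times; among named genes it ended the shoot call of PER2 (adjusted p = 0.0573) and the root call of a histone H4 gene, GRMZM2G181153 (0.0504). In roots, where the genotypes' libraries were taken to share only a number although each correlated best with its own, the block gave 26 introns and 41 isoforms. There the introns of GRMZM2G083620 at 898735 to 899108 (adjusted p = 0.0948) and of GRMZM2G159389 (0.0864) were not called. Nor were T01 of GRMZM2G083620 (0.0965), T02 of GRMZM2G130432 (0.0543), T03 of GRMZM2G170382 (0.0705) and T04 of GRMZM5G841900 (0.1201). Of the lists, an estimated correlation left 0 in roots and 0 in shoots, fry gave 0 in roots and 4 in shoots (1, 3), quantile scaling 6 in roots (1, 5) and equal sums 4 in shoots (2, 2). Genes called in the same direction in both tissues numbered 209, and 42 with an adjusted p under 0.01 (33, 9), where fewer calls enter. Chromosomes that passed in roots or shoots numbered 0, and 1 with quantile scaling.

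Leaving out 1 library in turn gave 221 to 1775 genes in roots, 301 to 1205 in shoots, 1329 to 2796 averaged over tissues, 1 to 79 for the interaction, 4928 to 7758 between tissues in wild type and 3201 to 4802 in rgh3. It gave 21 to 79 introns in roots, 10 to 42 in shoots, 19 to 140 isoforms in roots, 15 to 59 in shoots, 4 to 12 lists in roots and 3 to 9 in shoots. At 0.455 M fragments, rgh3 shoot replicate 3 lists more genes at 0 than the other libraries, so falls of low genes in shoots are the least certain; without it 725 of the 1130 shoot genes, all 960 root genes and 41 of the 76 interaction genes were called in the same direction.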

Other observations

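The comparison with windows over the genome, the test of intron length and the count of splits that keep the pairs were chosen after the results had been seen. The other tests here were set down after the calls but before the result each one measures was seen.

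In rgh3 shoots sodC, dhar4 and the glutathione reductase gene gar2 (GRMZM2G429000), all of the list of peroxidases and oxidant scavenging, were lower than in wild type, while camera did not call that list (adjusted p = 0.486). The gar2 gene fell from 1027 ± 566 to 166 ± 76.3 FPKM (SD, n = 3; log2 -2.54, SE 0.63, limma adjusted p = 0.0444), a call lost in 8 of the 12 fits without 1 library, with an adjusted p of up to 0.193 without wild-type shoot replicate 3. Of the 23 tested members of the list 1 rose and 4 fell in shoots. The member that rose, PER2, went from 0.526 ± 0.624 to 6.19 ± 4.64 (log2 3.11, adjusted p = 0.0428), and with the replicate block its adjusted p was 0.0573.

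Genes near the Rgh3 models may carry a haplotype linked to the mutation. Of 327 tested genes within 10 Mb on either side, 36 (11.0%) were called in roots or shoots, against 7.24% elsewhere (odds ratio 1.59, Fisher's exact test, two-sided, p = 0.0133). Of those 36, 15 were higher in at least 1 tissue. Of 175 windows of that width over the genome, 4 had a share as high, the highest 13.6%. The excess may come from linkage. Windows around the Rgh3 models were not left out and neighbouring windows overlap, so whether other regions reach such a share is not shown.

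In roots, genes with a called intron had a lower median change of their total level between genotypes than other genes with tested introns. The median log2 change was -0.40 over 33 genes and -0.06 over 4464 others, a difference of -0.34 (permutation test, p = 0.00263). In shoots the difference was -0.22 over 25 and 4472 genes (permutation test, p = 0.0591), which leaves it open. At the gene level 2 of the root genes were called higher and 4 lower, and in shoots 0 were called higher and 2 lower by limma. The permutation test takes genes as units, from the same libraries that gave the intron calls. Its p-value does not measure the spread between libraries. That retention goes with a fall of the total level in roots is therefore only a possibility, and most of these genes were not called. The 42 introns called higher in either tissue had a median length of 132 bp against 117 bp for the others, a difference of 15 bp (permutation test, p = 0.215), so a difference in length was not shown.

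Splits of the 6 libraries of a comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. Every other split also mixes the genotypes or tissues within its groups. A real difference then widens the spread, so low counts in other splits do not show how many calls chance would give. The real split gave 960 genes in roots and the highest other 2, and the real split was in each case the 1 with the most calls. The corresponding counts were 1130 and 3 for shoots, 6294 and 0 for the tissues in wild type, 4543 and 5 for the tissues in rgh3, 37 and 0 for introns in roots, 30 and 3 for introns in shoots, 58 and 2 for isoforms in roots and 31 and 4 for isoforms in shoots. Among splits that part as many same-number pairs, the highest other count was 3 for shoot genes, 1 for shoot introns and 0 for shoot isoforms and for the tissues in either genotype. For the average over tissues, 1 of 100 splits reached the real count of 2315, the real one itself, and the highest other gave 273. Only 4 splits keep the pairs that the numbers form in shoots and between tissues, too few for a share under 0.05, and the highest other of these gave 2.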
